A study of Mus musculus with 8 samples.

How the data were processed

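ZBTB2, a protein with a BTB domain and zinc fingers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against GFP. The cells were mouse embryonic stem cells (ESCs, line IB10) carrying a GFP-tagged ZBTB2 on a bacterial artificial chromosome (BAC), and neural progenitor cells (NPCs) derived from them. Of the 8 samples, 3 had a peak list and were analysed: tagged ESCs in serum with LIF, tagged ESCs in serum with LIF plus 2i (a pair of kinase inhibitors), and tagged NPCs. The other 5 samples, which were 3 inputs and 2 GFP immunoprecipitations from untagged cells, are not analysed here. The untagged cells were serum ESCs and NPCs, so 2i ESCs had no untagged sample. The untagged NPCs came from another ESC line (R1) than the tagged NPCs.

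Each list gives the chromosome, start, end, name and score of each peak, with no header. Peak positions are in mm9, per the submitters' processing notes, which also name MACS2 2.0 and SAMtools. The score was deposited by the authors and was read as the −log10 of the peak caller's p or q value, because its lowest value in each list lies just above −log10 of the cutoff in the name of the deposited list (0.001 for both ESC lists, 0.01 for NPC). Which of p and q it is, the aligner, the control library used for calling and the meaning of the word merged in the names of the lists are not given in the sources used here. The number of reads behind each list is unknown. A score grows with sequencing depth and depends on the control, so scores were used to rank and bin peaks within a list and for rank correlations between lists, and values of different lists are set side by side without a test.

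Each group had 1 library, so no difference between conditions has a replicate check and no p-value is given for one. Peaks were called shared when they overlapped by at least 1 bp. Shares carry 95% Clopper-Pearson intervals, which treat peaks as independent and cover counting error only. As background, the other list's peaks were placed at random 100 times on their own chromosomes with their widths kept. A chromosome's length was taken as the last peak end in any list, since no mm9 genome was used. Random placement ignores that promoters and mappable sequence attract peaks of any factor, so it is a low bar. Overlapping peaks of the 3 lists were also merged into regions, each with the highest score per list. Peaks of 1 list at most 10 kb apart were joined into chains. Medians carry order-statistic intervals. Spearman correlations are across peaks, which are not independent replicates. Starts are given 1-based.

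Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The functions were tested on simulated lists of 4072 peaks, as many as in the serum list. Planted overlaps, merged regions and a planted chain were recovered with a difference of 0, and the share under random placement came within 0.117 percentage points of its expected value. The shared counts of the deposited lists were checked against bedtools 2.31.1 and were equal for every pair of lists.

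The named peaks followed a rule fixed before the data were examined, as were the comparisons and most alternatives. The rule takes the 10 highest-scored peaks of each list, the 10 highest-scored regions shared by all 3 lists (ranked by serum score), and the 10 highest-scored peaks of each ESC list absent from the other, with the same for NPC against both. The regions in all 3 lists were to lie at transcription start sites. That condition was dropped because the gene table at hand belongs to another build (GRCm38.p6), and coordinates were not converted. For the same reason the planned shares of peaks at start sites and in CpG-rich sequence, the sequence motifs and the tests of 20 gene lists are not analysed here, and peaks are named by position. The rule would also have named the Zbtb2 gene itself in every case, which was not placed on mm9 here. Alternatives tried were other overlap rules, the higher-scored 50% of each list, lists of matched length, an NPC score above 3 and leaving out a dense block of peaks on chromosome 10.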

Results

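ZBTB2-GFP peaks were compared between 3 cell states: ESCs in serum with LIF (serum ESCs), ESCs in the same medium with 2i added (2i ESCs), and NPCs. Each state was represented by 1 library and 1 peak list. The serum list held 4072 peaks covering 1891 kb, the 2i list 5934 peaks covering 2562 kb and the NPC list 320 peaks covering 103 kb. Read depth was unknown. The NPC list had a looser cutoff in its name than the ESC lists, and 4 NPC peaks scored at or below 3, the ESC cutoff on the −log10 scale. The GFP immunoprecipitations of untagged cells were not analysed here, so background of the antibody was not checked. Whether the peak calling took it into account is unknown, because the control library is not given.

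Peaks were short in all 3 lists. Median width was 380 bp (quartiles 258 and 592) in serum ESCs, 330 bp (219 and 549) in 2i ESCs and 262.5 bp (200.5 and 380.5) in NPCs. The median score, the −log10 of the caller's p or q value, was 15.3, 12.2 and 11.2 in the same order, and the highest score was 404.8, 220.8 and 205.2. Wider peaks had higher scores within each list, with a Spearman correlation across peaks of 0.71 in serum ESCs, 0.70 in 2i ESCs and 0.42 in NPCs.

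Chromosome X held few peaks. It carried 37 serum peaks, or 0.909% of the list (95% interval 0.641 to 1.25), 66 2i peaks, or 1.11% (0.861 to 1.41), and 4 NPC peaks, or 1.25% (0.342 to 3.17). The NPC share was 0.629% without the 2 peaks at the distal end of X and 1.88% in the higher-scored 50% of the list. Chromosome X makes up 6.34% of the span of the numbered chromosomes and X as the peaks delimit it. Per Mb it had 0.222 serum peaks, below the lowest autosome (chromosome 14, 1.02), and 0.397 2i peaks, again below the lowest autosome (chromosome 13, 1.54). In NPCs it had 0.0240 peaks per Mb against 0.0603 on chromosome 6, the lowest autosome. The densest autosome in both ESC lists was chromosome 11, with 2.73 serum and 3.27 2i peaks per Mb, and in NPCs it was chromosome 17 with 0.242. No peak lay on chromosome Y. These densities are by span only and do not allow for promoters, mappable sequence or the number of X copies per cell.

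**Figure D1:**
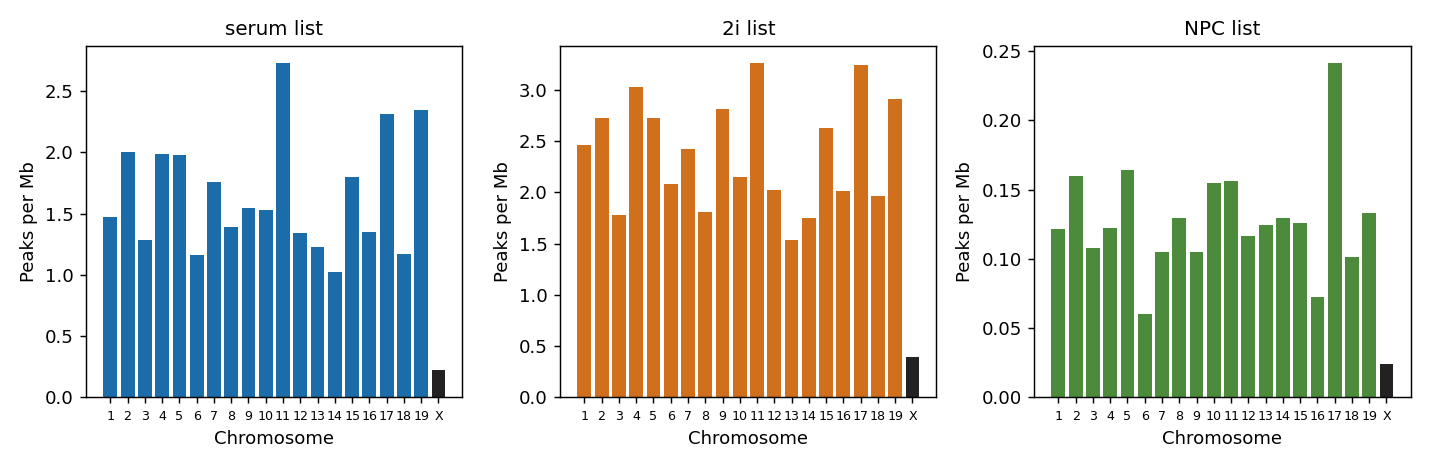
Peaks per Mb of chromosome span (y axis, starting at 0, a separate scale for each list) on each autosome and on X (black bar) in the serum, 2i and NPC lists. X is the lowest bar in each list, at 0.222, 0.397 and 0.0240 peaks per Mb.

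The first comparison asked whether the culture medium changed where ZBTB2 was found in ESCs. Most serum peaks were also 2i peaks: 3236 of 4072, or 79.5% (95% interval 78.2 to 80.7), overlapped a 2i peak, against a mean of 0.221% (range 0.0246 to 0.417) over 100 random placements. In the other direction 3167 of 5934 2i peaks, or 53.4% (52.1 to 54.6), overlapped a serum peak, against 0.157% (0.0337 to 0.337) at random. With the 2i list reduced to its 4072 highest-scored peaks, the length of the serum list, the shares were 68.6% and 65.9%. The centres of overlapping peaks lay a median of 53 bp apart.

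Peaks found in both media were the stronger and wider ones of each list. Shared serum peaks had a median score of 18.6 (95% interval 17.8 to 19.3) and serum peaks without a 2i partner 9.78 (9.25 to 10.04), with median widths of 438 and 248 bp. Shared 2i peaks had a median score of 18.8 (18.1 to 19.5) and unshared ones 9.01 (8.74 to 9.27), with widths of 492 and 236 bp. From the lowest to the highest score quartile the share of serum peaks with a 2i peak rose from 60.4% to 98.4%, and that of 2i peaks with a serum peak from 23.7% to 92.1%. Across the 3236 shared serum peaks the scores in the 2 lists had a Spearman correlation of 0.59.

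**Figure D2:**
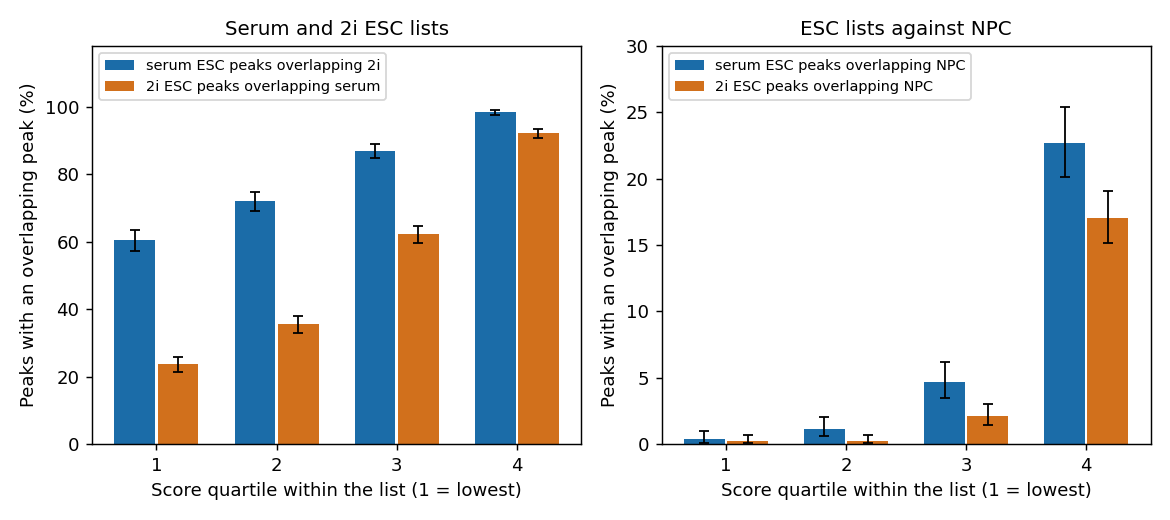
Share of peaks (y axis, percent) that overlap a peak of the other list, by score quartile within the list (x axis, 1 is the lowest), with 95% Clopper-Pearson intervals as error bars. Left, serum against 2i ESCs; right, each ESC list against NPCs, on a y axis ending at 30%. Every series is highest in quartile 4, at 98.4% and 92.1% on the left and 22.7% and 17.0% on the right.

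The strongest sites were common to both media. All 10 top serum peaks overlapped a 2i peak and all 10 top 2i peaks a serum peak, and 5 were in the top 10 of both lists. The peak on chromosome 9 at 108392723 to 108393530 ranked first in serum ESCs with a score of 404.8, and its 2i partner scored 215.8. On chromosome 15, the peak at 99125216 to 99125859 ranked first in 2i ESCs with 220.8, and its serum partner scored 366.4. The peak on chromosome 4 at 132833121 to 132833982 scored 352.9 in serum and 214.3 in 2i ESCs. A 2i peak on chromosome 12, at 92577085 to 92577774, stood apart from the other top 2i peaks: it scored 161.9 in 2i ESCs and its serum partner 18.7, while the serum partners of the other 9 scored between 110.03 and 404.8.

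No peak listed in a single medium was among the 100 highest-scored of its list. Among serum peaks without a 2i partner the highest was on chromosome 8 at 73397121 to 73397685, with a score of 59.8 and rank 313 in the list. Next came peaks on chromosome 8 at 127316780 to 127317423 (score 48.1), chromosome 10 at 59342167 to 59342836 (47.8) and chromosome 11 at 53113643 to 53114351 (47.1). Among 2i peaks without a serum partner the highest was on chromosome 2 at 30548870 to 30549224, with a score of 66.2 and rank 176. It was followed by peaks on chromosome 11 at 12367174 to 12367658 (63.4), chromosome 18 at 24625359 to 24625715 (56.6), chromosome 17 at 25023620 to 25023969 (55.3) and chromosome 1 at 71699194 to 71699963 (52.0). None of the 10 highest 2i-only peaks overlapped an NPC peak. Of the 10 highest serum-only peaks, 1 did, on chromosome 3 at 133902811 to 133903322, with scores of 33.3 in serum ESCs and 17.7 in NPCs.

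The second comparison asked how ZBTB2 sites in NPCs relate to those in ESCs. Nearly all NPC peaks lay at ESC peaks: 308 of 320, or 96.25% (95% interval 93.5 to 98.0), overlapped a serum peak, and 307, or 95.9% (93.2 to 97.8), a 2i peak. Random placement gave means of 0.131% and 0.169%, with no draw above 0.938%. With either ESC list counted, 312 NPC peaks were shared. Conversely, 295 serum peaks, or 7.24% (6.47 to 8.08), and 293 2i peaks, or 4.94% (4.40 to 5.52), overlapped an NPC peak. The serum share was 1.77% under a reciprocal overlap of 50% and 41.9% among the top 320 peaks of each list. The 2i share was also 41.9% among the top 320. NPC peaks were narrow parts of ESC peaks, with a median width ratio of 0.36 to the serum partner. Under a reciprocal overlap of 50% the NPC shares were 22.5% for serum and 20% for 2i, whereas 94.1% and 94.7% of NPC peaks had 50% or more of their own length inside a serum or 2i peak.

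NPC peaks were found mainly at the strong ESC sites. Serum peaks with an NPC peak had a median score of 55.7 (95% interval 51.5 to 61.3) and those without 14.3 (13.99 to 14.8). For 2i peaks the medians were 48.1 (42.4 to 52.1) and 11.8 (11.5 to 12.0). An NPC peak was present at 0.393% of serum peaks in the lowest score quartile and at 22.7% in the highest. Among shared peaks the NPC score had a Spearman correlation of 0.47 with the serum score and 0.36 with the 2i score. At the 290 serum peaks that overlapped both an NPC and a 2i peak, the serum and 2i scores had a correlation of 0.75. At lists of equal length, the top 320 of each, 45.0% (39.5 to 50.6) of NPC peaks overlapped a serum peak, against 56.9% (51.2 to 62.4) of serum peaks that overlapped a 2i peak. The top 320 were the whole NPC list, down to its cutoff, but only the highest-scored part of each ESC list. The 2 shares are therefore not like for like.

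Some of the strongest ESC sites had no NPC peak. Of the regions in both ESC lists without an NPC peak, the 3 with the highest serum scores are given here, a choice made after their values were seen. The region on chromosome 11 at 3996350 to 3997018 scored 211.8 in serum and 109.6 in 2i ESCs. The region on chromosome 4 at 102786694 to 102787693 scored 200.5 and 111.4, and the region on chromosome 17 at 35977871 to 35978930 scored 198.7 and 100.8. In the other direction, 8 NPC peaks overlapped neither ESC list. The highest of them, on chromosome 8 at 42533863 to 42534050, was 188 bp wide, with a score of 80.8 and rank 3 in the NPC list. The next, on chromosome 17 at 88853756 to 88853928 and on chromosome 10 at 52101677 to 52101924, scored 27.9 and 13.4, and the other 5 scored between 6.23 and 7.91. Of these 5, the peak on chromosome 10 at 5893169 to 5893340 (6.25) lay in the dense block described below. The peak on chromosome X at 166416823 to 166417167 (6.98) lay at the distal end of X.

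Merging the lists gave 6680 regions, of which 287 (4.30%) had a peak in all 3 lists and 2783 (41.7%) in both ESC lists but not in NPCs. A further 2763 regions were in the 2i list alone, 831 in the serum list alone and 8 in the NPC list alone, while 4 regions were shared by NPCs and serum ESCs only and 4 by NPCs and 2i ESCs only. Median scores over the regions in all 3 lists were 57.7 in serum ESCs, 49.2 in 2i ESCs and 11.8 in NPCs. The 10 regions in all 3 lists with the highest serum scores were also the top 10 of the serum list. Among them, the chromosome 9 region at 108392680 to 108393530 scored 59.6 in NPCs, the chromosome 15 region at 99125216 to 99125881 scored 56.6 and the chromosome 4 region at 132832998 to 132833982 scored 23.1.

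**Figure D3:**
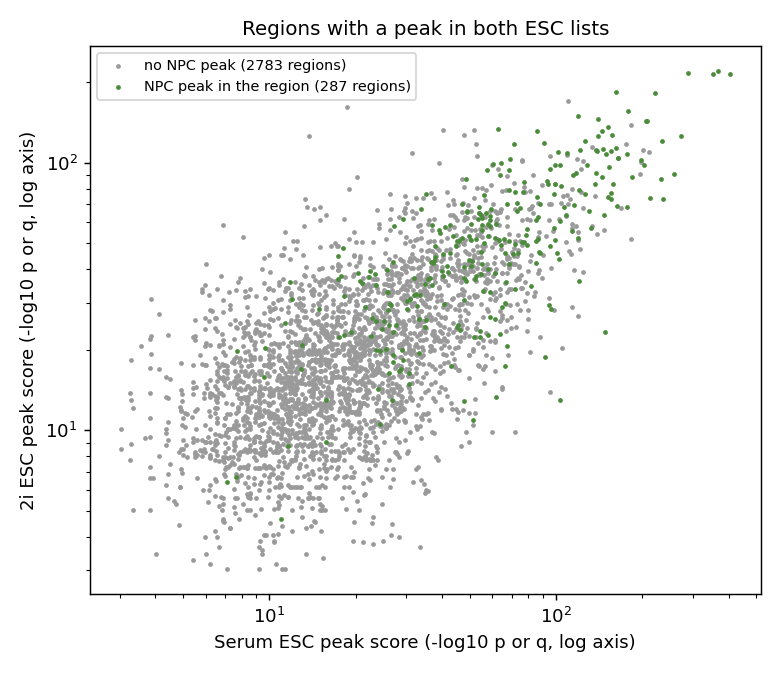
Scores (−log10 of p or q, log axes) of merged regions with a peak in both ESC lists, serum on the x axis and 2i on the y axis. Green points (287 regions) also have an NPC peak and gray points (2783 regions) do not; green points gather at high scores, with medians of 57.7 and 49.2, and gray points are present there too.

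A pair of regions on chromosome 10 led the NPC list. The region at 5957113 to 5960296 scored 288.0 in serum ESCs (rank 4), 216.6 in 2i ESCs (rank 2) and 205.2 in NPCs (rank 1). The region at 5913233 to 5914824 scored 234.9 (rank 8), 120.6 (rank 26) and 185.7 (rank 2). The next NPC peak scored 80.8. Both regions lay inside a segment of 150 kb, at 5852507 to 6002609, that held 83 peaks in 2i ESCs, 7 in serum ESCs and 5 in NPCs. Whether extra copies of a tagged BAC segment, taken up below, raised their scores was not tested. Outside it, the longest chain of 2i peaks had 10 peaks. The 83 peaks were 1.40% of the 2i list. The 7 serum and 5 NPC peaks came from shorter lists, of 4072 and 320 peaks.

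**Figure D4:**
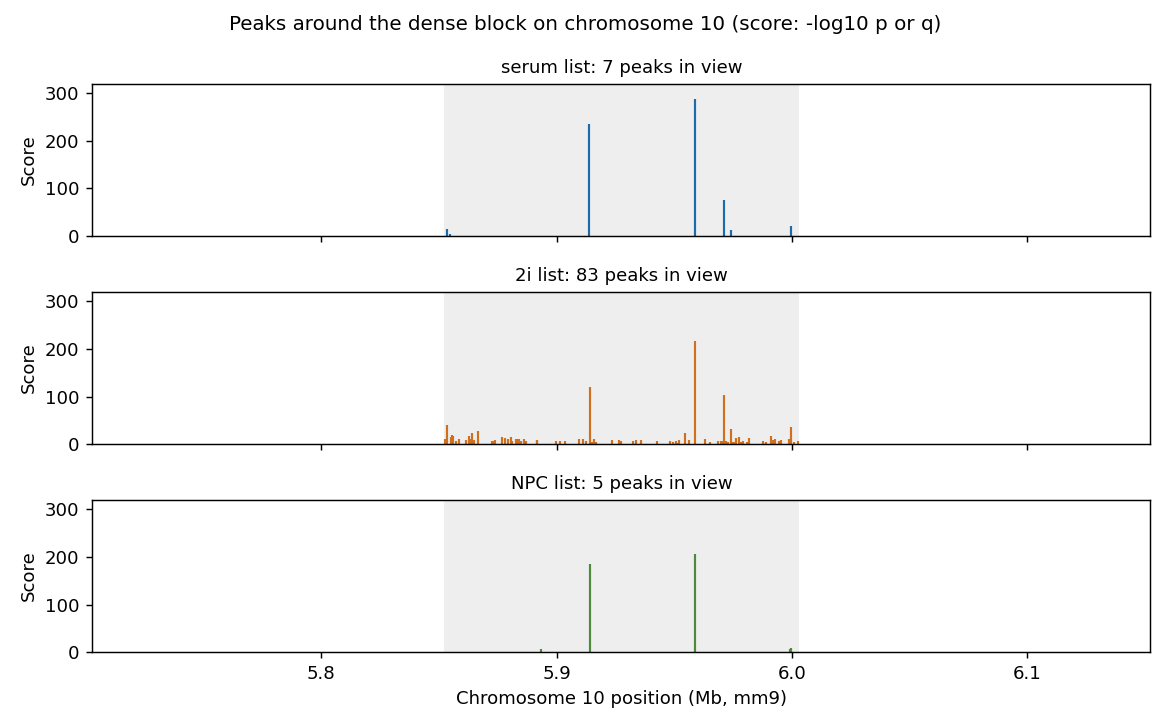
Peaks on chromosome 10 (x axis, Mb in mm9) in the serum, 2i and NPC lists, drawn as lines at the peak centre with the score (−log10 of p or q) as height. The gray segment of 150 kb holds 7 serum, 83 2i and 5 NPC peaks, and no peak is seen on either side of it.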

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

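The alternatives on the chromosome 10 block, the NPC score above 3, 50% of the counted peak, the regions in all 3 lists, the chromosome X share and the score correlation were chosen after seeing the data. Groups of 5 values are in the order serum in 2i, 2i in serum, NPC in serum, NPC in 2i and serum in NPC. A reciprocal overlap of 50% gave 62.1%, 42.6%, 22.5%, 20% and 1.77%, which for NPCs follows from their narrower peaks. Lists of matched length gave 68.6%, 65.9%, 45.0%, 44.7% and 41.9%: the 3 shares that fell had fewer peaks to meet, and for the 2 that rose (2i in serum and serum in NPC) the counted list was the one reduced to its top peaks. Joining peaks within 1 kb gave 83.0%, 57.9% and 8.50% for serum in 2i, 2i in serum and serum in NPC. Requiring 50% of the counted peak gave 73.3%, 46.8% and 1.79% for the same 3. The higher-scored 50% of each list gave 54.9% for 2i in serum, and 148 regions in all 3 lists in place of 287. At a score above the serum median of 15.3 the lists held 2036 serum, 2275 2i and 109 NPC peaks. The other 23 settings of these results, among them every one without the chromosome 10 block or with an NPC score above 3, stayed within the counting interval or within 1.5 times the count. Of 20 settings of the median scores, the chromosome X shares and the score correlation, 11 moved. Shared peaks kept a higher median score than unshared ones in all 6 directions under the reciprocal rule. For NPC peaks the intervals of the medians overlapped at a 1 bp overlap. NPC peaks shared with serum had a median of 11.3 (10.2 to 12.6) and unshared ones 8.30 (6.25 to 13.4). Against 2i the medians were 11.3 (10.2 to 12.6) and 7.91 (6.25 to 17.7). Alternatives on start sites, CpG content, gene lists and motifs were not run, because no mm9 genome or annotation was used. Depth is unknown, so what it limits cannot be stated as a number.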

Other observations

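The tests of the chromosome 10 block and of the 2i peaks below the top decile were chosen after the result was seen. Short chains of peaks recurred elsewhere. The lists were not filtered here for repeated sequence, so whether these chains are clustered binding was not tested. On chromosome 17, 10 serum peaks lay within 5.62 kb at 39980049 to 39985664, with a median score of 7.84, and 5 2i peaks lay at 39979977 to 39985767. The distal end of chromosome X held 10 2i peaks at 166421757 to 166443427, or 15.2% of all 2i peaks on X, against 2 serum peaks at 166424750 to 166440810 and 2 NPC peaks at 166416823 to 166425105. On chromosome 4, 6 2i peaks lay at 55477010 to 55493459. Of pairs of neighbouring peaks, 10.2% in serum ESCs, 10.4% in 2i ESCs and 5.72% in NPCs were at most 1 kb apart. A single 2i peak lay on the mitochondrial chromosome, and 8 serum, 8 2i and 3 NPC peaks lay on contigs of unknown position.

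The dense block on chromosome 10 is one that a biologist would want to look at again. Its 83 2i peaks were mostly weak, with a median score of 8.60 against 12.2 in the list, covered 23.2% of the segment and left no gap over 7408 bp. Extra copies of a tagged BAC segment are a candidate explanation, since a BAC carries a segment of about this length, but which genes the block holds was not looked up. The same would bear on the pair of regions in the block that led the NPC list, which was not tested either. The flanks, each as long as the block, held 0 2i peaks, where 0.729 would be there by chance at the median autosomal density. The chain rule itself left the first 10 kb of each flank empty and the block without a gap over 10 kb. No list had a peak between the start of chromosome 10 and the block, and the next 2i peak after it started at 7401020. A wide stretch without peaks can have another local cause too, so extra copies of a tagged BAC segment cannot be told apart from one by these counts. Per 100 kb the block held 55.3 2i, 4.66 serum and 3.33 NPC peaks, against median autosomal densities of 2.43, 1.53 and 0.125 per Mb. All 3 lists were thus denser there than at that median. The NPC list held 5 of its 320 peaks there, so it was not short of peaks for its length. Why the serum list held fewer peaks there than the 2i list, although the tagged cells descend from one line by their labels, stays open. Depth, the control library and the culture cannot be told apart, because no deposited value used here gives depth or control.

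Peaks listed in only 1 ESC culture may be sites that fell just under the cutoff in the other library. Below the top decile this stays open. In the lowest score decile 76.7% of 2i peaks had no serum peak, and in the ninth 10.5%. This restates the gradient that prompted the test, and weak sites specific to a medium would give it too. The same overlaps counted from the serum peaks give no independent check. By that count 42.3% of serum peaks in the lowest decile and 1.72% in the ninth had no 2i peak. Of the 408 serum peaks in the top decile, 1 had none. In the top decile, 10 of the 590 2i peaks outside the block had no serum peak, none of these lay within 1 kb of one, and 1 further peak had its partner in the lowest serum decile, at scores up to 6.69. The serum partners in this decile had a median score of 53.6 and a 5th percentile of 17.0, so few listed partners lay near the cutoff. These values cover only partners that passed the serum cutoff, so they do not show the serum signal at the 10 peaks without one. They do not exclude scatter around the calling threshold, because the bound set for exclusion took peaks as replicates. With 1 library per medium, scatter between libraries is not separated from the medium or from the control library, which is unknown. Scatter and a dependence on the medium therefore cannot be told apart.

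The NPC list may be short because its library was less sensitive at every site. That would leave the strongest ESC sites in place only if NPC scores followed ESC scores closely. Among shared peaks the NPC score had a Spearman correlation of 0.47 with the serum score. Of the 54 regions in the top 100 of both ESC lists, 12, or 22.2% (95% interval 12.0 to 35.6), had no NPC peak. Their median serum score was 154.3, against 157.3 for the 42 with one. Exclusion also required at least 5 NPC peaks at regions in the lower 50% of both ESC lists, and only 4 of 562 such regions had one, so a uniform loss cannot be told apart from a loss at chosen sites. The NPC peak on chromosome 8 at 42533863 to 42534050, with a score of 80.8 and no ESC partner, is not accounted for by lower sensitivity; whether it is background of the antibody was not tested, since the untagged NPC library is not analysed here.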
